A study of Homo sapiens with 15 samples.

How the data were processed

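RNA was measured in 15 libraries of MCF7 cells, an established breast cancer cell line, in 4 groups defined by the ESR1 form expressed (WT or Y537N) and by E2 (0 or 20 nM for 24 h). Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded, poly(A)-selecting mRNA kit. The labels also give genomic DNA as the molecule, which the extraction protocol does not bear out, and the values were treated as RNA. Per the submitters' processing notes, STAR 2.7.3a, Partek and the hg19 build were used; the annotation and the strand setting of counting are not given in the sources used here.

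The authors deposited a single table with samples in rows and 19773 genes in columns, in CPM after TMM normalization, per the file headers. The CPM values sum to 769289 to 850154 per library. They are not counts. The value of 1 read was estimated in each library from the steps between low values, and 78.0% to 81.6% of low values were whole reads within 0.02 reads, so whole reads were not recovered and no count model was used. That value gave an estimated depth of 15000000 to 102000000 reads in genes: 17500000 to 33400000 in WT without E2, 27800000 to 102000000 in WT with E2, 15900000 to 67600000 in Y537N without E2 and 15000000 to 67700000 in Y537N with E2, each to 3 significant digits. The 10 most abundant genes held 5.08% to 6.09% of the CPM.

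Each table row names its receptor form and treatment, which gave its group; the rows carry no replicate number of the labels, so they were used as unnumbered replicates. Library names end in r for 3 libraries (S7r, S8r, S16r), with no explanation in the sources used here. All of them had E2, S7r and S8r in WT and S16r in Y537N cells. Whatever the mark stands for is therefore partly mixed with the E2 effect and the interaction. No pair of libraries was a duplicate: within groups the Pearson correlation of log2 values was 0.996 to 0.998, and the mean squared difference was 2.45 to 34.2 times the counting noise over 21 pairs, against 25.2 to 274 over 84 pairs between groups.

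Values were transformed as log2(CPM + 1), and genes with at least 1 CPM in at least 3 libraries were kept (13999 of 19773). All 15 libraries entered 1 limma model with the 4 groups and moderated variances with a mean-variance trend. The E2 effect within each receptor form, the difference between the forms at each E2 level and the interaction were tested, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Of 16 gene lists fixed before the data were examined, 15 had members among the tested genes; the list of mitochondrially encoded genes had 0 genes in the table. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation: 50 of 75 tests passed with the first and 8 with the second. The estrogen score was compared with two-sided exact permutation tests.

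Named genes followed a rule set before the data were examined. For each pairwise comparison it took the 6 largest rises and 6 largest falls past the threshold with complete separation of the groups and at least 5 CPM in the higher group, and up to 3 members of each list with the smallest adjusted p. For the interaction it took the 5 most positive and 5 most negative terms at a mean of at least 5 CPM. ESR1, TFF1, PGR, GREB1 and PDZK1 were always included, and genes chosen after their values were seen are marked so.

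The model was tested on simulated data with known changes. Of genes changed 1.5-fold it recovered 95.9% for E2 in WT, 98.0% for E2 in Y537N, 93.9% for Y537N without E2, 95.9% for Y537N with E2 and 87.8% for the interaction. Of genes changed 1.25-fold it recovered 85.7%, 81.6%, 85.7%, 87.8% and 51.0% in the same order. Each of these rates rests on 49 genes. The simulation gave every gene the same relative spread and changed far fewer genes than were called in the data. The rates in the data may therefore differ, above all for genes with low values. Alternatives covered the pseudocount (0.1 and 5), the filter, 3 other scalings (each library to the same sum, median-of-ratios, quantile), the variance model, the libraries in the fit and leaving out each library. A scan of neighbouring genes used the gene order of GRCh38.p14, in which 13566 of the 13999 tested genes had a match; no coordinates were taken from it. Tools were R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.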

Results

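RNA of MCF7 cells, an estrogen receptor-positive breast cancer cell line, was measured by stranded mRNA sequencing in 15 libraries. The cells expressed either wild-type ESR1 (WT), which encodes estrogen receptor alpha, or ESR1 with the Y537N substitution, a change in the ligand-binding domain found in breast cancers that resist endocrine therapy. They were kept in medium with hormone-stripped serum, with or without 20 nM estrogen (E2) for 24 h. There were 4 libraries of WT cells without E2, 3 of WT cells with E2, 4 of Y537N cells without E2 and 4 of Y537N cells with E2. Values are in CPM, the reads of a gene scaled to the size of its library, for 19773 genes. Of these 13999 passed the filter on low values and were tested. The estimated depth was 15000000 to 102000000 reads in genes per library. Gene lists were tested with camera in limma, Benjamini-Hochberg adjusted, at a preset correlation. Where that call was lost with an estimated correlation, the latter adjusted p is given beside the list. Fold changes are differences of mean log2(CPM + 1) with their standard error, and understate the change of genes near the floor. Libraries are named by the numbers of the deposited table (S1 to S16r). Nothing in the labels says that replicates came from separate cultures, so the p-values measure the spread between these libraries only. Receptor form and cell population go together here, so no difference between WT and Y537N cells can be assigned to the receptor alone.

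ESR1 RNA was present in every group and was lower with E2 and lower in Y537N cells. Its mean was 350 ± 8.87 CPM (SD, n = 4) in WT cells without E2, 221 ± 5.57 (n = 3) in WT cells with E2, 269 ± 12.1 (n = 4) in Y537N cells without E2 and 183 ± 7.74 (n = 4) in Y537N cells with E2. The log2 change with E2 was -0.66 ± 0.04 in WT and -0.55 ± 0.04 in Y537N cells (limma with Benjamini-Hochberg adjustment, adjusted p = 8.74e-12 and 1.13e-10). The difference of Y537N from WT was -0.38 ± 0.04 without E2 and -0.27 ± 0.04 with E2 (limma, Benjamini-Hochberg adjusted p = 9.77e-08 and 2.92e-05). Gene-level values do not separate the introduced ESR1 from the cells' own, nor the mutant from the wild-type sequence.

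The first comparison asked what E2 changes in cells with wild-type receptor. Textbook receptor targets rose. PDZK1, a scaffold protein of membrane transporters, went from 4.01 ± 0.782 CPM (SD, n = 4) to 44.5 ± 2.92 (n = 3), and PGR, the progesterone receptor, from 17.9 ± 2.42 to 130 ± 13.6. TFF1, a secreted trefoil peptide, rose by 1.68 ± 0.08 and GREB1, a receptor cofactor, by 1.44 ± 0.05 on the log2 scale. Of 48 measured estrogen-induced genes 45 rose and 0 fell, among them the protease PRSS23 (2.61 ± 0.04), CXCL12, a chemokine (2.63 ± 0.05), and EGR3, an immediate early transcription factor (2.99 ± 0.07). All 30 genes of G2/M and mitosis rose, with CDK1 at 1.16 ± 0.04 and CCNB1 at 1.09 ± 0.04. In G1/S and DNA replication 31 of 34 genes rose and 1 fell, with RRM2 at 0.96 ± 0.04 and TYMS at 0.91 ± 0.04 (list adjusted p = 0.0825 with an estimated correlation).

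Ribosome biogenesis genes rose with E2 in WT cells in 25 of 26 cases and fell in 1, with NOP56 at 1.03 ± 0.04 (list adjusted p = 0.0825 with an estimated correlation). Sterol synthesis genes rose in 21 of 27 cases and fell in 2, with the squalene epoxidase SQLE at 1.03 ± 0.04 and CYP51A1 at 0.89 ± 0.04 (list adjusted p = 0.0825 with an estimated correlation). Of 30 interferon-stimulated genes 23 rose and 3 fell, led by IFI6, which went from 17.7 ± 2.15 to 109 ± 14.5 CPM, and OAS3 (1.11 ± 0.05). Of 24 antigen processing and presentation genes 16 rose and 2 fell, with the peptide transporter subunit TAP2 at 0.96 ± 0.05 and HLA-A at 0.90 ± 0.06. Both list calls were lost (adjusted p = 0.232 with an estimated correlation). Of 22 hypoxia and glycolysis genes 15 rose and 2 fell (list adjusted p = 0.580 with an estimated correlation). The unfolded protein response list went both ways, 13 rising and 7 falling, with the chaperone HSPA5 at 0.82 ± 0.04 and HERPUD1 at -1.20 ± 0.05 (list adjusted p = 0.404 with an estimated correlation). Besides PDZK1 and EGR3, the largest rises were AREG, an EGF receptor ligand (3.10 ± 0.09), PGLYRP2 (2.98 ± 0.09), CALB2 (2.96 ± 0.09) and IL24 (2.85 ± 0.06).

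Falls with E2 in WT cells were led by PSCA, which dropped from 20.8 ± 1.20 to 0.410 ± 0.0702 CPM, and by SERHL2, WNT2B, KCNK12, CELF3 and ABCA4, with log2 changes from -3.72 ± 0.08 to -2.77 ± 0.07. Of 24 estrogen-repressed genes 17 fell and 4 rose, with YPEL3 at -2.60 ± 0.06 and BCAS1 at -2.11 ± 0.06 (list adjusted p = 0.160 with an estimated correlation). Luminal epithelial genes fell in 17 of 23 cases and rose in 4, with the transcription factors SPDEF at -1.83 ± 0.05 and GATA3 at -0.92 ± 0.04 (list adjusted p = 0.232 with an estimated correlation). Of 25 p53 target genes 15 fell and 5 rose, with TP53INP1 at -1.99 ± 0.06 and the cell cycle inhibitor CDKN1A at -0.93 ± 0.05 (list adjusted p = 0.232 with an estimated correlation). Immediate early genes (7 rose, 7 fell of 22), mesenchymal and basal genes (7 rose, 5 fell of 15) and markers of stromal, endothelial and blood cells (0 rose, 2 fell of 5) did not pass as lists.

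In all, 4806 genes rose and 4643 fell with E2 in WT cells (limma, Benjamini-Hochberg adjusted p under 0.05), of which 311 and 416 changed at least 2-fold. The balance depended on the scaling: 50.9% of the calls were rises, and 42.6% (4117 rises, 5553 falls) with each library rescaled to the same sum. Adjusted over the list alone, 18 estrogen-repressed genes and 2 G1/S genes fell, 17 antigen presentation genes and 6 p53 targets rose, and the other list counts were the same. The calls of the estrogen-induced and G2/M lists held with an estimated correlation (camera in limma, both Benjamini-Hochberg adjusted p = 0.00702). The call for the unfolded protein response list stood at adjusted p = 0.0489 (camera in limma, Benjamini-Hochberg) and was lost in several settings, with adjusted p = 0.0508 at a pseudocount of 5 and 0.0512 to 0.0617 without any 1 of S2, S3, S6, S9 to S13 and S15. At a mean of at least 20 CPM the hypoxia and p53 calls were lost (camera in limma, Benjamini-Hochberg adjusted p = 0.111 and 0.0546).

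**Figure D1:**
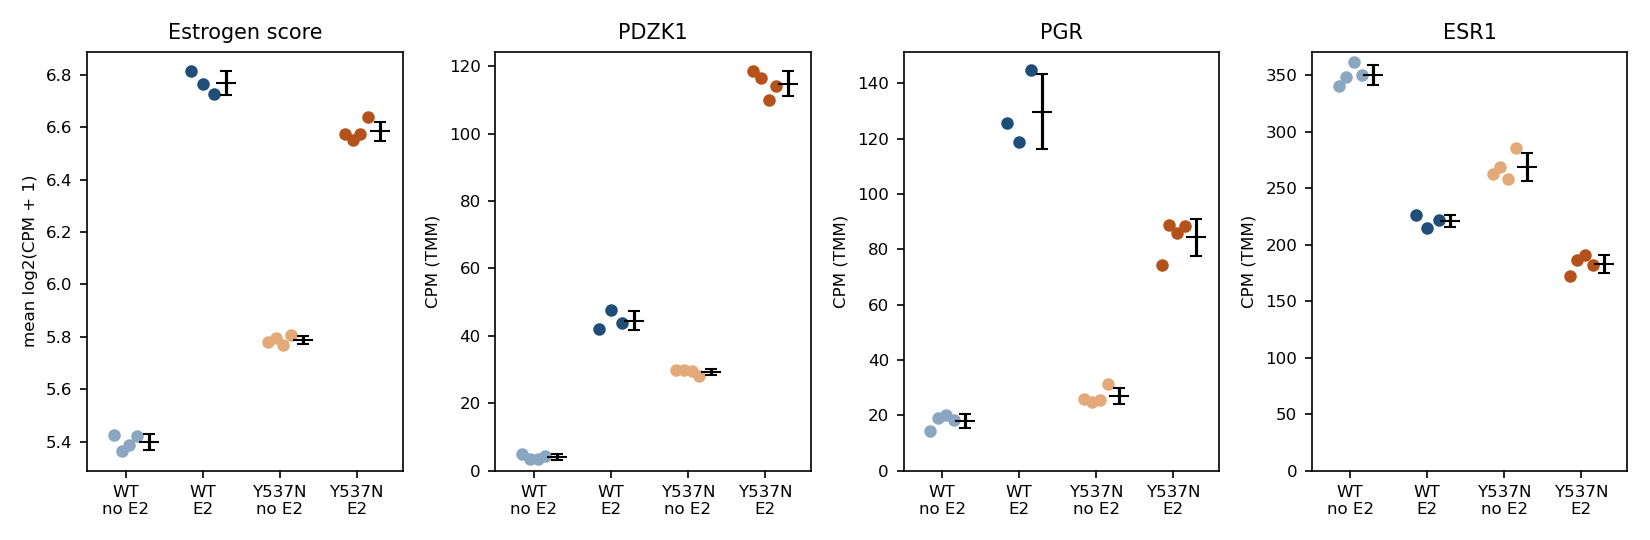
Values of each library (points) with the group mean and SD (black bars) for the estrogen score, the mean log2(CPM + 1) of 48 estrogen-induced genes, and for PDZK1, PGR and ESR1 in CPM. The score was 5.40 in WT cells without E2, 5.79 in Y537N cells without E2, 6.58 in Y537N cells with E2 and 6.77 in WT cells with E2, and its axis does not start at 0.

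The second comparison asked the same of cells with Y537N receptor. The textbook targets rose here as well. PDZK1 went from 29.3 ± 0.876 to 115 ± 3.69 CPM (SD, n = 4 each), PGR from 26.8 ± 2.92 to 84.3 ± 6.78. GREB1 and TFF1 rose by 0.85 ± 0.05 and 0.52 ± 0.08 on the log2 scale. Of the 48 estrogen-induced genes 44 rose and 2 fell, with PRSS23 at 1.94 ± 0.04, CXCL12 at 1.37 ± 0.05 and PKIB at 1.16 ± 0.04. All 30 G2/M genes rose, with HMMR at 0.94 ± 0.04 and KIF20A at 0.85 ± 0.04. In the G1/S list 29 of 34 genes rose, and in the ribosome biogenesis list 25 of 26 rose and 1 fell (both list adjusted p = 0.103 with an estimated correlation). Sterol synthesis genes rose in 24 of 27 cases and fell in 1, with HMGCR, the rate-limiting enzyme of cholesterol synthesis, at 0.94 ± 0.03 and PCSK9, which lowers LDL receptor levels, at 2.07 ± 0.10.

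Of 24 antigen processing and presentation genes 14 fell and 4 rose with E2 in Y537N cells, with the transcription factor IRF1 at -0.77 ± 0.06 and the peptide-loading protein TAPBP at -0.55 ± 0.04. The list call was lost (adjusted p = 0.459 with an estimated correlation), also at a mean of at least 20 CPM (camera in limma, Benjamini-Hochberg adjusted p = 0.0576). Interferon-stimulated genes went both ways, 11 rising and 10 falling of 30, with IFI44L at 0.93 ± 0.08 and STAT2 at -0.34 ± 0.04. Estrogen-repressed genes fell in 14 of 24 cases and rose in 5, with YPEL3 at -2.06 ± 0.06 and the protease inhibitor TIMP3 at -1.69 ± 0.05 (list adjusted p = 0.302 with an estimated correlation). Luminal genes fell in 13 of 23 cases and rose in 3 (list adjusted p = 0.459 with an estimated correlation). Of 22 hypoxia and glycolysis genes 16 rose and 1 fell, with the glucose transporter SLC2A1 at 0.87 ± 0.05 and ALDOC at 1.45 ± 0.11 (list adjusted p = 0.478 with an estimated correlation). Library S16r stood apart from its group in this list, with a mean log2(CPM + 1) of 6.40 against 5.48 to 5.86 in the other 3 libraries, and the list mean of 0.51 became 0.31 without it. The largest rises were TUBB2B (2.11 ± 0.15), SLC7A11, a cystine transporter (2.08 ± 0.11), PCSK9 and MAT1A (1.97 ± 0.13). The largest falls were the metallothionein MT1F (-2.88 ± 0.07), CHRD (-2.42 ± 0.10), TM4SF1 (-2.40 ± 0.10), PSCA (-2.36 ± 0.08) and KRT81 (-2.33 ± 0.11).

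In Y537N cells 4043 genes rose and 4289 fell with E2 (limma, Benjamini-Hochberg), 113 and 165 of them at least 2-fold. Rises were 48.5% of the calls, and 39.8% (3452 rises, 5222 falls) with each library rescaled to the same sum. They were 50.3% with median-of-ratios scaling and 50.7% with quantile normalization, so the majority turned with the scaling. Adjusted over the list alone, 25 sterol genes and 2 p53 targets rose, and the other counts were the same. Of 24 unfolded protein response genes 13 rose and 4 fell (list adjusted p = 0.249 with an estimated correlation). The interferon list did not pass, nor did the p53 targets (3 rose and 10 fell of 25), immediate early genes (8 and 9 of 22), mesenchymal and basal genes (7 and 3 of 15) or stromal and blood markers (0 and 2 of 5). With an estimated correlation the estrogen-induced, G2/M and sterol lists passed (camera in limma, Benjamini-Hochberg adjusted p = 0.00899, 0.00899 and 0.0161).

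**Figure D2:**
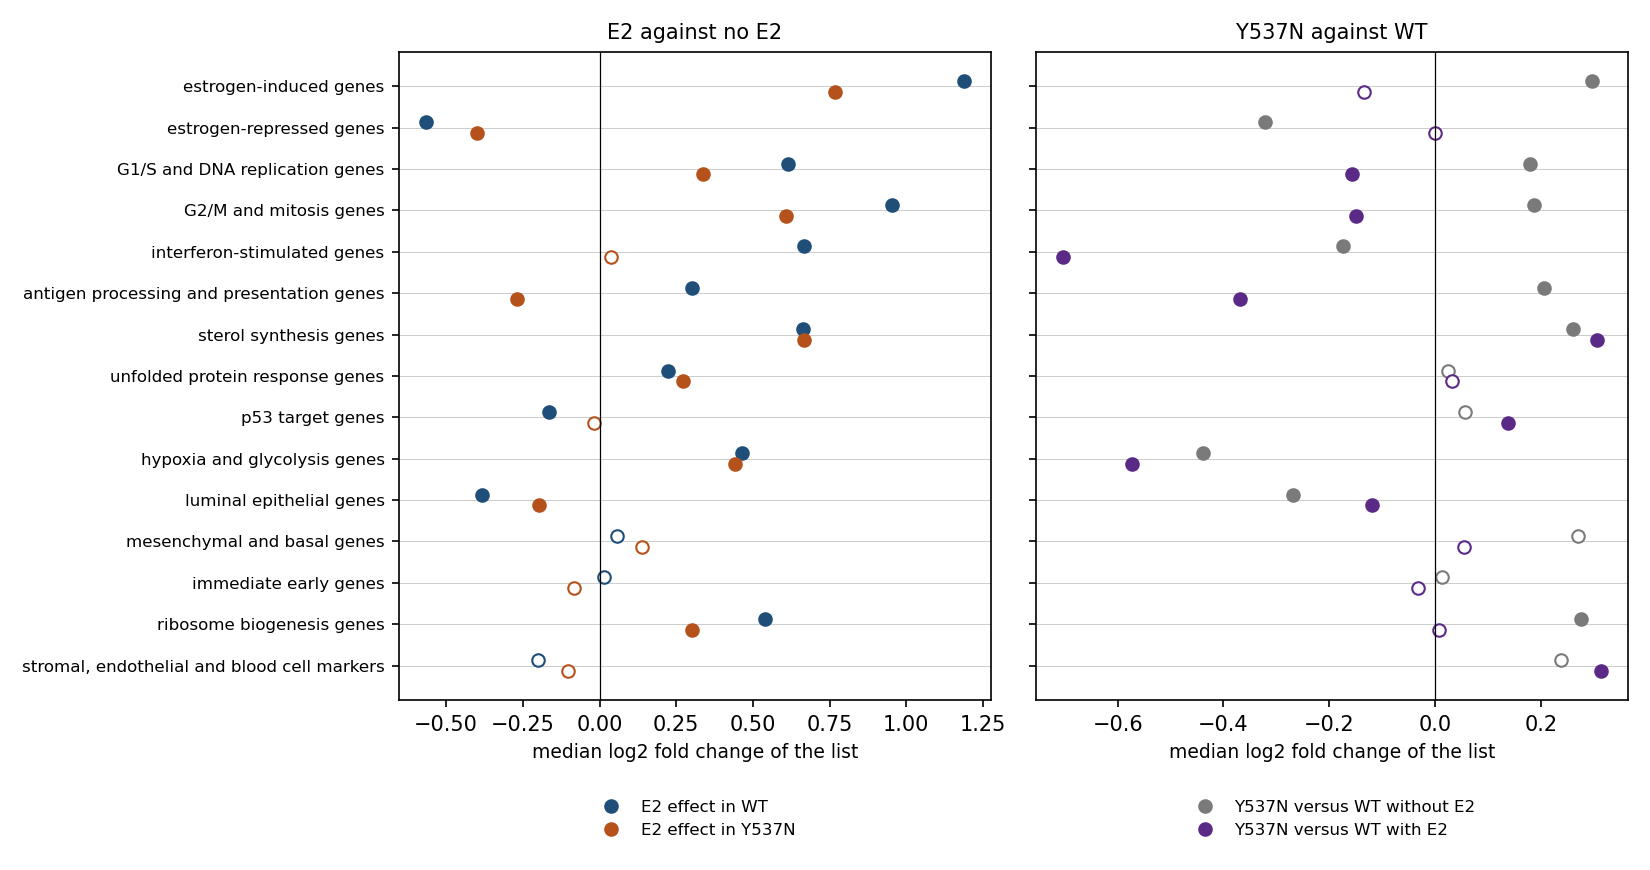
Median log2 fold change of each fixed gene list for the E2 effect with each receptor form (left) and for Y537N against WT at each E2 level (right). Filled points passed camera in limma at the preset correlation and open points did not. Antigen presentation genes had a median of 0.30 with E2 in WT and -0.27 in Y537N cells.

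The third comparison asked how Y537N cells differ from WT cells when no E2 is given. Of 48 estrogen-induced genes 31 were higher and 6 lower in Y537N cells, with PDZK1 at 2.61 ± 0.07, PRSS23 at 1.27 ± 0.04 and HSPB8 at 1.06 ± 0.05 (list adjusted p = 0.126 with an estimated correlation). PGR (0.56 ± 0.09) and GREB1 (0.42 ± 0.05) were higher, whereas TFF1 differed by 0.17 ± 0.08, which did not pass (limma, Benjamini-Hochberg adjusted p = 0.0754, and 0.0291 without S1, 0.0364 without S16r and 0.0287 with each library rescaled to the same sum). Estrogen-repressed genes were lower in 15 of 24 cases and higher in 5, with TIMP3 at -1.19 ± 0.05 and ERBB2 at -0.72 ± 0.04 (list adjusted p = 0.249 with an estimated correlation). Higher were 22 of 26 ribosome biogenesis genes, 19 of 27 sterol genes (1 lower, HMGCS1 at 0.58 ± 0.04) and 21 of 30 G2/M genes (AURKA at 0.29 ± 0.03). These 3 list calls were lost (adjusted p = 0.126 with an estimated correlation). Of 34 G1/S genes 23 were higher and 3 lower, with PCNA at 0.40 ± 0.04 (list adjusted p = 0.249 with an estimated correlation).

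Interferon-stimulated genes, of which most rose with E2 in WT cells, were lower in Y537N cells without E2 in 16 of 30 cases and higher in 3, with BST2, a membrane protein that tethers viruses, at -1.97 ± 0.06 and IFI6 at -1.29 ± 0.10 (list adjusted p = 0.379 with an estimated correlation). Hypoxia and glycolysis genes were lower in 18 of 22 cases and higher in 1, with BNIP3 at -1.36 ± 0.17 and NDRG1 at 12.9 ± 1.15 against 94.1 ± 18.1 CPM (list adjusted p = 0.379 with an estimated correlation). Luminal genes were lower in 17 of 23 cases and higher in 1, with SPDEF at -0.79 ± 0.05 and FOXA1 at -0.52 ± 0.04 (list adjusted p = 0.126 with an estimated correlation). Antigen presentation genes were higher in 15 of 24 cases and lower in 4, with the invariant chain CD74 at 1.38 ± 0.07 (list adjusted p = 0.252 with an estimated correlation). This rested on members with low values: the list mean of 0.25 was 0.03 among those with a mean of at least 20 CPM, and the call was lost (camera in limma, Benjamini-Hochberg adjusted p = 0.00111 and 0.466). Besides PDZK1, the largest differences were PEG10, an imprinted gene (3.04 ± 0.07), IL24 (2.36 ± 0.06) and TNFSF15 (1.87 ± 0.06) upward. Downward they were PRKAR2A, a regulatory subunit of protein kinase A (0.480 ± 0.108 CPM in Y537N against 16.6 ± 0.612 in WT cells), and TENM3 (0.781 ± 0.163 CPM in Y537N against 17.5 ± 0.691 in WT cells).

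Without E2, 3289 genes were higher and 3479 lower in Y537N cells (limma, Benjamini-Hochberg), 52 and 80 of them at least 2-fold. Higher genes were 48.6% of the calls, against 55.1% (3894 higher, 3176 lower) with each library rescaled to the same sum and 52.1% with median-of-ratios scaling, so the majority turned with the scaling. Adjusted over the list alone, 33 induced, 24 G1/S, 20 sterol and 23 ribosome genes and 6 repressed genes were higher, with the other counts the same. No list call held with an estimated correlation. The remaining lists did not pass: 6 higher and 7 lower of 24 unfolded protein response genes (median 0.02, mean -0.03), 7 and 2 of 25 p53 targets, 7 and 5 of 15 mesenchymal and basal genes, 8 and 3 of 22 immediate early genes, and 3 and 0 of 5 stromal and blood markers.

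The fourth comparison set the 2 receptor forms side by side with E2 present. Interferon-stimulated genes were lower in Y537N cells in 26 of 30 cases and higher in 2, with IFI6 at 9.13 ± 1.09 against 109 ± 14.5 CPM, BST2 at -2.55 ± 0.06 and IFI27 at -2.93 ± 0.13 (list adjusted p = 0.0801 with an estimated correlation). Antigen presentation genes were lower in 16 of 24 cases and higher in 4, with HLA-B at -1.54 ± 0.09 and HLA-A at -0.95 ± 0.06 (list adjusted p = 0.189 with an estimated correlation). Sterol genes were higher in 22 of 27 cases and lower in 0, with the fatty acid synthase FASN at 0.86 ± 0.05 and MVD at 0.79 ± 0.05 (list adjusted p = 0.0801 with an estimated correlation). Of 48 estrogen-induced genes 14 were higher and 23 lower. PDZK1 was higher (1.35 ± 0.08), while TFF1 (-0.99 ± 0.08), PGR (-0.62 ± 0.09), RET (-1.08 ± 0.05) and CXCL8 (-2.19 ± 0.10) were lower.

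Hypoxia and glycolysis genes were lower in 17 of 22 cases and higher in 0, with BNIP3 at -1.29 ± 0.18, although library S16r of the Y537N group lay above the other 3 in this list (list adjusted p = 0.527 with an estimated correlation). Of 30 G2/M genes 17 were lower, with TOP2A at -0.42 ± 0.04 (list adjusted p = 0.189 with an estimated correlation). Of 34 G1/S genes 20 were lower and 1 higher, with CCNE2 at -0.71 ± 0.07 (list adjusted p = 0.403 with an estimated correlation). Of 25 p53 targets 12 were higher and 3 lower, with BTG2 at 1.05 ± 0.06 and GDF15 at 0.92 ± 0.08 (list adjusted p = 0.0968 with an estimated correlation). Luminal genes were lower in 13 of 23 cases and higher in 3 (list adjusted p = 0.527 with an estimated correlation). Of 5 measured markers of stromal, endothelial and blood cells 4 were higher, including COL1A1, a collagen gene named here after its value was seen (0.69 ± 0.06); the list had adjusted p = 0.0801 with an estimated correlation. PEG10 (3.41 ± 0.08), the keratin KRT1 (2.96 ± 0.07), DIO2 (2.37 ± 0.09) and GPNMB (2.25 ± 0.06) had the largest upward differences. PRKAR2A (-3.58 ± 0.08), TNFRSF11B, a decoy receptor for RANKL (-3.31 ± 0.08), and TENM3 (-3.11 ± 0.10) were among the largest downward.

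With E2, 2461 genes were higher and 3448 lower (41.6% of the calls higher; limma, Benjamini-Hochberg), 92 and 106 of them at least 2-fold. With each library rescaled to the same sum 53.4% of the calls were higher. Without the 3 libraries marked r, S6 is the only WT library with E2. The median difference over all genes was then -0.05, against -0.03 with all libraries. GREB1 was lower by -0.17 ± 0.05, a call lost without S8r (-0.13) and with quantile normalization (-0.05) (limma, Benjamini-Hochberg adjusted p = 0.0116, and 0.0697 and 0.459). Without the 3 libraries marked r, with S6 alone for WT with E2, the GREB1 difference was -0.19. Adjusted over the list alone, 25 induced, 22 G1/S, 17 antigen and 14 luminal genes and 1 sterol gene were lower, 3 G1/S, 23 sterol, 4 luminal and 6 immediate early genes were higher, and the other counts were the same. Estrogen-induced genes did not pass as a list (camera in limma, Benjamini-Hochberg adjusted p = 0.0547, and 0.0308 to 0.0497 without any 1 of S4, S7r, S12, S13, S14 or S16r), nor did the repressed genes (9 higher, 9 lower of 24, but lower with adjusted p = 0.0460 at a mean of at least 20 CPM), the unfolded protein response (8 and 7 of 24), mesenchymal and basal genes (3 and 3 of 15), immediate early genes (5 and 6 of 22) or ribosome biogenesis genes (6 and 5 of 26). No list call held with an estimated correlation. The luminal call was also lost without S6 and at a mean of at least 20 CPM (camera in limma, Benjamini-Hochberg adjusted p = 0.0390, and 0.0694 and 0.0565).

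The last comparison asked where the E2 effect itself differs between WT and Y537N cells. KRT1 fell with E2 in WT cells (-2.07 ± 0.07) and rose in Y537N cells (1.18 ± 0.07), as did KRT16 (-0.58 ± 0.06 and 1.22 ± 0.06). GPNMB fell in WT cells (-1.99 ± 0.06) with 0.10 ± 0.05 in Y537N cells, and KCNK12 and ABCA4 fell less in Y537N cells. In the other direction, the chemokine CXCL8 rose in WT cells (2.28 ± 0.10) and fell in Y537N cells (-0.61 ± 0.09), as did RASGRP1 (1.70 ± 0.08 and -0.58 ± 0.08) and LINC01588 (1.62 ± 0.07 and -0.70 ± 0.07). PGLYRP2 rose in WT cells (2.98 ± 0.09) with -0.11 ± 0.08 in Y537N cells, and TNFRSF11B rose slightly in WT cells (0.28 ± 0.08) and fell in Y537N cells (-2.00 ± 0.07).

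Of 48 estrogen-induced genes 34 had a negative interaction and 2 a positive one, including TFF1 (-1.16 ± 0.11), PGR (-1.18 ± 0.13), PDZK1 (-1.26 ± 0.11) and GREB1 (-0.59 ± 0.07), while ESR1 had 0.11 ± 0.06, which did not pass. The interaction was negative for 26 of 30 G2/M and 18 of 24 antigen presentation genes, with TAP2 at -1.06 ± 0.07 and HLA-A at -0.84 ± 0.09. With an estimated correlation the estrogen-induced, G2/M and antigen presentation calls held (camera in limma, Benjamini-Hochberg adjusted p = 0.0204, 0.0204 and 0.0242). The interaction was also negative for 29 of 34 G1/S genes and positive for 1 (list adjusted p = 0.0827 with an estimated correlation), and negative for 17 of 26 ribosome genes (list adjusted p = 0.123 with an estimated correlation). Of 30 interferon-stimulated genes 21 had a negative and 1 a positive interaction, with IFI6 at -2.15 ± 0.15 (list adjusted p = 0.109 with an estimated correlation). The interaction was positive for 12 of 24 estrogen-repressed genes (4 negative; list adjusted p = 0.138 with an estimated correlation), 10 of 23 luminal genes (3 negative; 0.237) and 8 of 25 p53 targets (3 negative; 0.173). Sterol genes had a positive interaction in 9 and a negative one in 4 of 27 cases and did not pass as a list. The unfolded protein response (6 and 7 of 24), hypoxia (1 and 2 of 22), mesenchymal and basal (4 and 2 of 15), immediate early (3 and 6 of 22) and stromal and blood lists (1 and 0 of 5) did not pass either. The hypoxia list had a mean interaction of 0.04, and -0.30 without the libraries marked r, with S6 alone for WT with E2.

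The interaction passed for 3715 genes, 1616 positive and 2099 negative (limma, Benjamini-Hochberg). Its median over all genes was -0.02, and -0.05 without the 3 libraries marked r, which leaves S6 as the only WT library with E2. Adjusted over the list alone, 35 induced, 30 G1/S, 29 G2/M, 20 antigen and 21 ribosome genes had a negative and 15 repressed, 11 p53 and 11 luminal genes a positive interaction. On the same basis 3 induced genes were positive and 4 luminal genes negative, and the positive and negative counts were 10 and 5 for sterol, 6 and 8 for the unfolded protein response, 1 and 0 for hypoxia, 5 and 3 for mesenchymal and basal, 3 and 7 for immediate early and 2 and 1 for stromal and blood genes, adjusted over the list alone. Across genes, which are not independent replicates, the E2 effects of the receptor forms correlated with Pearson r = 0.816 and Spearman rho = 0.817, and the slope over the 9449 genes called in WT was 0.589.

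**Figure D3:**
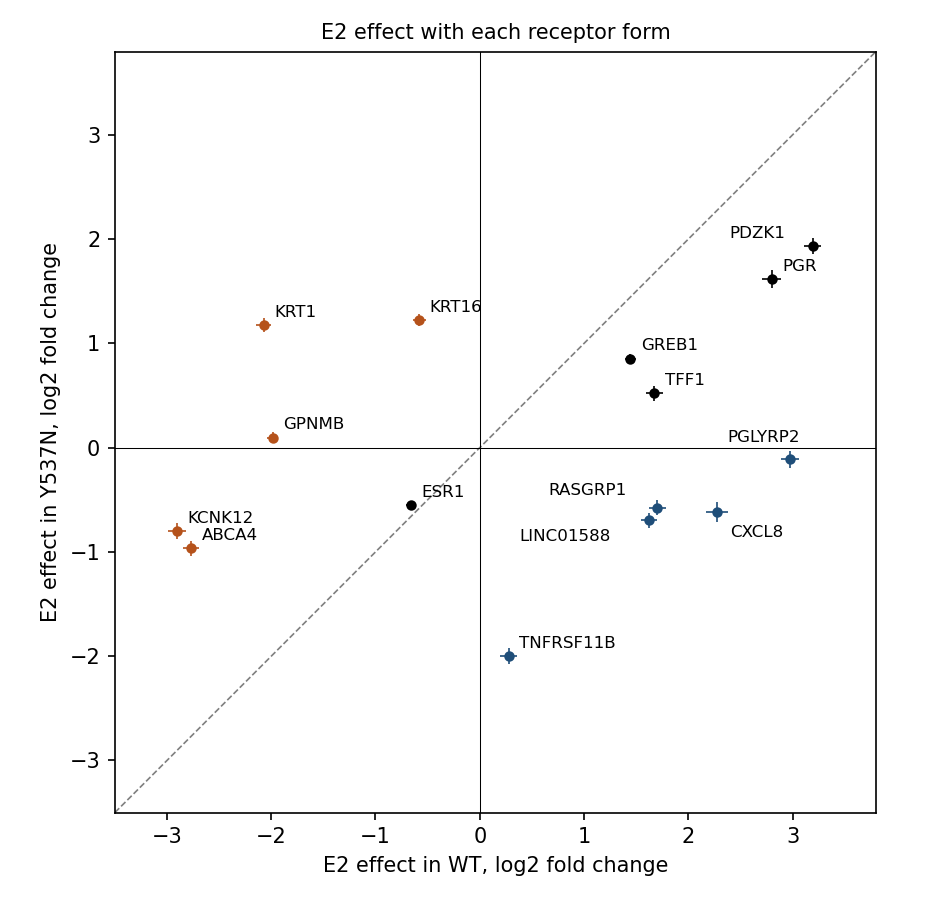
E2 effect in WT (horizontal) and Y537N cells (vertical) as log2 fold change with standard error, for the 5 most positive (orange) and 5 most negative (blue) interactions and for ESR1, TFF1, PGR, GREB1 and PDZK1 (black). The dashed line marks equal effects. PDZK1 lies at 3.19 and 1.94, and KRT1 at -2.07 and 1.18.

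The estrogen score, the mean log2(CPM + 1) of the 48 induced genes, summarised these differences per library. It was 5.40 ± 0.03 (SD, n = 4) in WT cells without E2 and 6.77 ± 0.04 (n = 3) with E2, and 5.79 ± 0.02 (n = 4) and 6.58 ± 0.04 (n = 4) in Y537N cells. Its 4 differences were 1.37 with E2 in WT, 0.80 with E2 in Y537N, 0.39 for Y537N without E2 and -0.19 for Y537N with E2, each with complete separation of the libraries. Each had p = 0.0286 in a two-sided exact permutation test, the smallest these group sizes allow, and 0.0286 after Benjamini-Hochberg adjustment over the 4.

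The E2 response in WT cells and the Y537N difference without E2 overlapped. Both were upward for 2256 genes (1129 for independent lists) and downward for 2240 (1154), and 367 and 349 genes went opposite ways (limma calls). Fold changes correlated across genes with r = 0.505 and a covariance of 0.0723. Both comparisons share the WT libraries without E2, and simulated unchanged groups against those controls gave r = 0.462 and a covariance of 0.00275. With the controls split between the comparisons, r was 0.461 to 0.489 and the covariance 0.0678 to 0.0713.

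Values of PDZK1, SERHL2, KRT16, KRT81, MT1F and the HLA genes are less certain than their errors show, since near-identical copies can share their reads. For genes that overlap on opposite strands the counting's strand setting is not given in the sources used here.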

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

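The split counts of the pairwise comparisons and the test of copy number as the whole cause were planned before their results were seen, and the split count of the interaction, the chromosome window, the estrogen-like direction, the tests on S16r and the tests of the smaller E2 response were chosen after theirs.

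The E2 effect differed between receptor forms by the interaction term of limma for 3715 genes (Benjamini-Hochberg), which drew attention to 9 lists and 52 of the 65 genes examined. The median interaction was -0.45 for estrogen-induced, 0.28 for estrogen-repressed, -0.32 for G1/S, -0.31 for G2/M, -0.59 for interferon-stimulated, -0.65 for antigen presentation, 0.14 for p53, 0.16 for luminal and -0.24 for ribosome genes.

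Positive interactions were KRT1 3.25, KCNK12 2.10, GPNMB 2.08, ABCA4 1.80, KRT16 1.80, PSCA 1.58, BCAS1 1.57, SERHL2 1.43, WNT2B 1.43, CELF3 1.12, TP53INP1 1.12, HERPUD1 0.88, SPDEF 0.86, YPEL3 0.54, PCSK9 0.49, CDKN1A 0.46, SLC2A1 0.43, GATA3 0.23 and HMGCR 0.21 (log2). Negative interactions were PGLYRP2 -3.09, CXCL8 -2.89, LINC01588 -2.32, TNFRSF11B -2.28, RASGRP1 -2.28, IFI6 -2.15, CALB2 -1.52, AREG -1.36, MT1F -1.31, PDZK1 -1.26, CXCL12 -1.25, PGR -1.18, TFF1 -1.16, EGR3 -1.08, TAP2 -1.06, IL24 -0.99, OAS3 -0.94, HLA-A -0.84, IRF1 -0.84, PRSS23 -0.67, MAT1A -0.65, GREB1 -0.59, NOP56 -0.58, CDK1 -0.57, TYMS -0.56, TAPBP -0.54, TIMP3 -0.53, NOLC1 -0.34, RRM2 -0.31, CCNB1 -0.29, SQLE -0.24, CYP51A1 -0.23 and HMMR -0.18.

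In 18 of 351 tests of a group of 4, a single library lay far from the other 3, and how often chance gives this was not tested. In WT without E2 these were S1 for BIRC5 (75.6 CPM), GDF15 (23.1 CPM), LINC01588 (11.4 CPM) and PRSS23 (61.7 CPM), and S2 for MVD (64.7 CPM), NDRG1 (121 CPM) and WNT2B (22.4 CPM). In Y537N without E2 they were S11 for IFI27 (0.534 CPM), IRF1 (27.4 CPM), PCSK9 (3.93 CPM) and SQLE (158 CPM), and S12 for PGR (31.1 CPM), SLC7A11 (4.86 CPM) and TP53INP1 (32.5 CPM). In Y537N with E2 they were S15 for DIO2 (9.71 CPM), S14 for the G1/S score (6.25), and S16r for SCNN1G (2.15 CPM) and the mesenchymal and basal score (2.93). Some gaps were small, as for that G1/S score (6.29 to 6.30 in the other libraries) and for MVD (69.0 to 69.8 CPM). Others were larger, as for NDRG1 (83.6 to 87.9 CPM in the other libraries).

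Regrouping the libraries argues against a chance division of these libraries for the 4 pairwise counts of genes. It cannot exclude a chance difference between cultures, since nothing in the labels says that replicates came from separate cultures. For E2 in WT, 1 of 35 splits, the real one, gave as many genes (9449, highest other 6413), and the same held for E2 in Y537N (1 of 35; 8332, highest other 0), Y537N against WT without E2 (1 of 35; 6768, highest other 6) and with E2 (1 of 35; 5909, highest other 3806). The 4 high splits in each comparison of 3 with 4 libraries (5914 to 6413, and 1225 to 3806 genes) keep 1 real group whole, so they measure the real difference in part. Redrawing the E2 labels within each receptor form, which gave up to 4595 genes against 3715, takes away the E2 effect as well and so does not test the interaction. With the additive effects of E2 and Y537N removed first, 1 of 100 splits, the real one, gave as many genes (3715, highest other 3133). That other split has 1 library on the wrong side of the interaction, so it measures the real difference in part. The result argues against a chance division of these libraries, with the same limit as above.

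The smaller E2 response of estrogen-induced genes in Y537N cells (mean interaction -0.57) remained with each library rescaled to the same sum (-0.56), which argues against the scaling factors. It also remained in the 40 members at 20 CPM or more with a pseudocount of 0.1 (-0.51), which argues against compression of low values. The raised level without E2 made up 67.5% of the difference. The score with E2 was lower in Y537N by -0.19 (two-sided exact permutation p = 0.0286, the smallest possible). Its 48 members went both ways there, 14 higher and 23 lower, and did not pass as a list (camera in limma, Benjamini-Hochberg adjusted p = 0.0547). For the score, the lower level with E2 argues against the raised level without E2 as the whole cause. A weaker response of the mutant receptor to E2 may account for the rest, as a hypothesis that was not tested. ESR1 RNA was also lower in Y537N cells (-0.38 without and -0.27 with E2). The introduced ESR1 is not separated from the cells' own, so the response cannot be assigned to the mutant receptor. A difference between the cell populations that does not come from the receptor stays open and was not tested.

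Of the genes tested, 1288 were higher and 1728 lower in Y537N cells at both E2 levels (limma calls). Estrogen-like activity of the mutant receptor was tested with separate WT libraries for the E2 effect and the Y537N differences. Over 18 splits, 65.3% to 76.3% of the genes also called for E2 went its way. This was short of the 90% set for it as the whole cause, but in 3 splits above the 75% set for excluding it. The lone WT library with E2 in each difference was assumed to vary like the others, so the splits do not decide. With all libraries, 2044 of the genes were also called for E2 in WT, and 582 of these went against it. In that count the shared WT libraries without E2 favour agreement with the E2 effect, and those with E2 favour opposition. With no WT library shared, 270 to 359 genes went against the E2 effect. Their direction is not the one that estrogen-like activity predicts, but the set bound for excluding it was not met in every split. As the whole or a part of the cause it stays open. In gene order the most one-sided window of 100 neighbours, on chromosome 6 from FAM50B to HMGN4, had 92% of its genes lower in Y537N, against at most 79% in 1000 shuffles and 79% for the E2 effect. A copy-number difference between the cell populations is a candidate explanation for that stretch, with medians of -0.27 without and -0.31 with E2. It is argued against for the whole pattern by a separate scan with windows of 50 neighbours: 7.94% of the genes, against 4.73% of all genes, lay in windows more one-sided than any of 200 shuffles, in 9 stretches.

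Library S16r (Y537N with E2) had a hypoxia and glycolysis score of 6.40 against 5.86, 5.48 and 5.48 in the rest of its group, with all 22 members above the mean of those libraries and NDRG1 at 83.0 CPM against 27.3, 8.76 and 7.85. A difference in depth is argued against by S14, which, with 67700000 estimated reads against 49100000 in S16r, had a lower score (S14 minus S16r, -0.92), and by the Y537N libraries without E2, whose scores lay between 5.27 and 5.32 at 15900000 to 67600000 reads. Handling shared by the libraries marked r cannot be told apart: S7r and S8r lay below S6 on average (-0.25), but S6 is the single library without the mark in its group. RN7SL2 (481 CPM against 32.5 to 49.0), which has near-identical copies, and BCYRN1 (491 against 159 to 194), chosen after their values were seen, were also higher in S16r. The cause stays open, and no biological explanation was tested.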

How the results depend on the processing

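The alternatives without the libraries marked r and with a mean of at least 20 CPM were chosen after seeing the data. No paired analysis was possible because the table's libraries carry no replicate number of the labels, so they match groups only; a count test on recovered reads was not run, as whole reads were not recovered. ESR1 kept its direction and call in each pairwise comparison under every alternative tried. For the named genes, 1758 of 1765 values under other settings kept direction and call, with 2 weaker and 5 stronger, and 2277 of 2280 did when a library was left out. Most of these genes were picked for large changes or small adjusted p in these data, so this does not measure the stability of other calls. For lists, 826 of 885 did, with 52 weaker, 5 stronger and 2 in the other direction, and 1109 of 1125 did when a library was left out. With a mean of at least 20 CPM the gene counts were 5434 (E2 effect in WT), 4815 (E2 effect in Y537N), 4062 (Y537N versus WT without E2), 3521 (Y537N versus WT with E2) and 2376 (Interaction of E2 and Y537N), since fewer genes were tested. Without the 3 libraries marked r the Interaction of E2 and Y537N gave 2423 genes, with fewer libraries. Of the gene list tests, 8 passed with an estimated correlation. Sharing of the E2 response and the Y537N difference had r = 0.478 at a pseudocount of 0.1 and 0.532 at 5, and the cause was not tested; with the controls split, which removes the shared libraries and leaves fewer, r was 0.472, 0.489, 0.474, 0.464, 0.461 and 0.478. Leaving out a library, the estrogen score differences were 1.35 to 1.39 (E2 effect in WT), 0.78 to 0.81 (E2 effect in Y537N), 0.37 to 0.40 (Y537N versus WT without E2) and -0.21 to -0.16 (Y537N versus WT with E2); where p passed 0.05, the smaller groups allow no smaller adjusted p. Estrogen-repressed genes, Y537N versus WT with E2, had a mean of -0.16 at 20 CPM or more, in the other direction and past the threshold, unlike before (camera in limma, Benjamini-Hochberg adjusted p = 0.0460). Hypoxia and glycolysis genes had a mean interaction of -0.30 without the libraries marked r, also in the other direction. In WT with E2 that setting keeps S6, which had the highest hypoxia score of its group (6.56, against 6.26 in S7r and 6.35 in S8r). In Y537N with E2 it drops S16r, the highest of its group (6.40, against 5.86, 5.48 and 5.48 in S13, S14 and S15). Both changes lower the interaction, and what sets these libraries apart was not tested. For the estrogen-repressed list the cause was not tested. Of the smallest simulated changes, 51.0% were recovered for the interaction.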

Other observations

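The list tests on NF-kappaB and stratified epithelium genes and on metallothioneins were set after the leading genes had been seen and before the values of the other members were seen; the members seen were left out, and the example genes were chosen after their values were seen.

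NF-kappaB and acute-phase genes, a group that inflammatory signals raise, differed between the receptor forms in their E2 effect. Of 14 members 10 rose and 1 fell in WT cells (median 0.48), and 1 rose and 12 fell in Y537N cells (median -0.54). The call in WT was lost (camera in limma, Benjamini-Hochberg adjusted p = 0.00587, and adjusted p = 0.13 with an estimated correlation), and that in Y537N held (adjusted p = 0.0222 with an estimated correlation). Without E2, 13 were higher and 1 lower in Y537N cells (median 0.72), and with E2 2 were higher and 11 lower (median -0.46). The interaction was negative for 12 and positive for 1 (median -1.23), with IL32 at -2.08, CXCL1, a chemokine, at -1.67 and RELB, an NF-kappaB subunit, at -1.29 (camera in limma, Benjamini-Hochberg adjusted p = 1.1e-13, and adjusted p = 0.000602 with an estimated correlation). E2 may lower this group in Y537N cells relative to its effect in WT cells, as a hypothesis from these libraries.

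Stratified epithelium genes, which include cornified envelope proteins, had a positive interaction for 10 and a negative one for 1 of 16 members (median 0.52), with SPRR1B at 2.06, SPRR1A at 1.16 and IVL, involucrin, at 0.98 (camera in limma, Benjamini-Hochberg adjusted p = 5.97e-07, and adjusted p = 0.0225 with an estimated correlation). With E2, 4 rose and 8 fell in WT cells, which did not pass (camera in limma, Benjamini-Hochberg adjusted p = 0.306). In Y537N cells 10 rose and 1 fell, a call that was lost (camera in limma, Benjamini-Hochberg adjusted p = 0.000829, and adjusted p = 0.104 with an estimated correlation). E2 may raise this group in Y537N cells relative to WT cells, as a hypothesis. Besides MT1F, 2 metallothionein genes were measured, MT1X at 0.27 with E2 in WT and -0.69 in Y537N cells, and MT2A at 0.66 and -0.34, too few to test E2 lowering metallothionein genes as a family.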
